A study of Ovis aries with 2 samples.

How the data were processed

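Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on conceptuses, the embryo with its extraembryonic membranes, flushed from ewes on day 14 of pregnancy. Per the labels, material of 4 conceptuses from separate ewes was pooled, giving 1 library precipitated with a rabbit polyclonal antibody against PPARG and 1 input library of unprecipitated chromatin. Tissue was fixed with formaldehyde and sheared by sonication. There are no replicate libraries, so no spread between animals can be given and no test was made between ChIP and input.

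The submitters' processing notes name BWA as a tool and Oar_v3.1 as the genome build. The version of BWA, the peak caller, its threshold, the read filters and the gene annotation are not given in the sources used here. The deposited table lists intervals per library, without saying whether each library was called on its own, and all 5 input intervals have the bounds of a ChIP interval. It gives the highest and the mean signal of a density track in each interval, as deposited by the authors without a stated unit or scaling between libraries. The mean signal times the number of bins was a whole number, within 0.01, in 100% of the listed intervals, and bins measured 31.9 bp. The signal is treated here as fragment density of unknown scaling. The total read number of each library is unknown, so no counting interval is given for a height. The authors' table also gives for each interval the number of CpG islands, the number of promoters, the assigned genes, the signed distance to each gene's start and whether it lies upstream, in the gene or downstream. These distances run from the summit of the interval: for all 211 named genes with at least 2 intervals on a chromosome, the summits and distances gave a single gene start. Upstream assignments reached 10470 bp. Among intervals with a single assigned gene, those marked with a promoter lay between -8387 and 2885 bp of the gene start. Heights are the authors' own and served only to describe and rank intervals within this list. Positions are printed as the file gives them.

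Intervals were read in Python 3.11.15 with pandas 2.3.3 and tests were run with scipy 1.17.1. The table paired 2160 intervals and genes and used 1833 gene names, of which 146 were LOC identifiers, 28 were tRNA names and 1659 were other names. Of these last, 1520 (91.6%) matched a symbol or synonym of the 16387 named protein-coding genes on chromosomes in the RefSeq gene table of assembly ARS-UI_Ramb_v3.0. That assembly differs from Oar_v3.1, so the table served only for names, and none of its coordinates was used. Of the matched names, 6 were found through the table's synonyms. The other 139 names, some of them older symbols, were not mapped, so their genes count as having no interval. Because the authors' table uses some older names, well-studied genes may be named in both more often than others, which can raise the excess of any list of well-studied genes. Lists for unrelated tissues and a background of the other lists' genes bear on this.

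For each of 18 gene lists, fixed before the data were examined, the members with an assigned interval were counted. The share was compared with that of all 16387 named genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05. Odds ratios carry exact conditional 95% intervals and shares carry Wilson 95% intervals. These intervals cover counting error over genes or intervals only. Genes are not replicates, and each p-value describes this list of intervals. On simulated assignments, which drew each of 16387 genes independently and used lists without common genes, the test called 78.0% of lists with a planted 4-fold excess, 20.5% of those with a 2-fold excess and 0.708% of lists with none. These rates do not cover gene length, overlapping lists or intervals shared between genes. In the data, 442 of the 2288 intervals were assigned to 2 or more genes. Heights of classes of intervals were set beside the medians of 2000 random sets of the same number of intervals.

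The design had foreseen random lists matched on gene length, random placement of the intervals, 20 sequence motifs including the PPAR response element, and other windows around genes. No genome sequence or annotation of Oar_v3.1 was used here, so these were not run. The unmatched Fisher's exact test, planned as an alternative, became the test of the gene lists. Concentration at gene starts was instead measured within the authors' distances, against a uniform spread over the 10 kb upstream of a start, with an exact binomial test chosen after the data were seen. Intervals within 1 kb of a gene's own start were counted as a version of the list test that does not depend on gene length. Gene families defined by symbol patterns (8 families, tested with 3 unions of them, 11 tests per setting) were also added after the data were seen. Family names that the table lacks were left out, and a second count added them as members. Such names are known only from the intervals. Over all intervals each of them therefore counts as having one, which makes the second count an upper one. In all, 19 alternatives were fixed beforehand and 7 were added.

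Genes were named by a rule fixed before the data were examined. It took the 20 highest ChIP intervals assigned to a named gene and without an input height of at least 50% of the ChIP height, up to 4 members of each list with the highest intervals, PPARG and RXRA, the 3 names with the most intervals, and the 3 intervals highest in the input. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here.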

Results

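The study asked where the nuclear receptor PPARG binds the genome of the sheep conceptus on day 14 of pregnancy, and which genes lie at those sites. PPARG (peroxisome proliferator-activated receptor gamma) is a ligand-activated transcription factor that binds DNA as a dimer with a retinoid X receptor and is best known as a regulator of lipid metabolism. The conceptus comprises the embryo and its extraembryonic membranes, of which the trophectoderm is the outer epithelium. The data consisted of 1 PPARG ChIP-seq library and 1 input library, each from a pool of 4 conceptuses. Neither library was replicated, so the values below carry no biological error, and the read totals behind them are unknown. Heights are the highest fragment-density signal in an interval, as the authors' peak caller gave it, and positions refer to build Oar_v3.1.

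The PPARG library yielded 2288 intervals and the input library yielded 5. PPARG intervals had a median height of 22 signal units, with quartiles of 17 and 31 and a range from 10 to 155. Their median length was 876 bp, and together they covered 2144 kb. Each of the 5 input intervals had the same bounds as a PPARG interval. The highest of them, on chromosome 9 from 52248478 to 52249237 with no gene assigned, reached 93 in the input and 123 in the ChIP, a ratio of 1.32, and ranked 2 by height among the PPARG intervals. The next, on chromosome 2 from 161512004 to 161512809 and also without an assigned gene, reached 43 in the input and 88 in the ChIP. The third lay in EMCN, an endothelial sialomucin gene, on chromosome 6 from 24335986 to 24336650, with 38 in the input and 60 in the ChIP. Inside CD276 the heights were 19 and 78, and at an unassigned site on chromosome 7 they were 23 and 83. How the authors scaled the libraries to one another is not given in the sources used here, so these ratios rank the sites and do not measure enrichment.

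PPARG intervals lay close to gene starts more often than an even spread would give. Of the 2288 intervals, 410 (17.9%, 95% interval 16.4 to 19.5) had their summit within 1 kb of an assigned gene start, 711 (31.1%, 29.2 to 33.0) within 5 kb and 940 (41.1%, 39.1 to 43.1) within 10 kb. At least 1 gene body contained the interval in 845 cases (36.9%). A further 537 intervals (23.5%) were upstream of a gene and in none, and 136 (5.94%) were only downstream. No gene was assigned to 770 intervals (33.7%). Among 519 intervals upstream of a single gene and within 10 kb of it, 205 (39.5%, 35.4 to 43.8) lay in the nearest 1 kb, against 10% for an even spread, a 3.95-fold excess (exact binomial test, two-sided, p = 3.1e-70). The farthest 1 kb of the same window held 27 (5.20%). CpG islands, the GC-rich stretches found at many promoters, were marked in 568 intervals (24.8%). Promoter-marked intervals held one in 423 of 749 cases (56.5%), and other intervals in 145 of 1539 (9.42%). An interval lay within 1 kb of at least 2 gene starts in 56 cases.

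**Figure D1:**
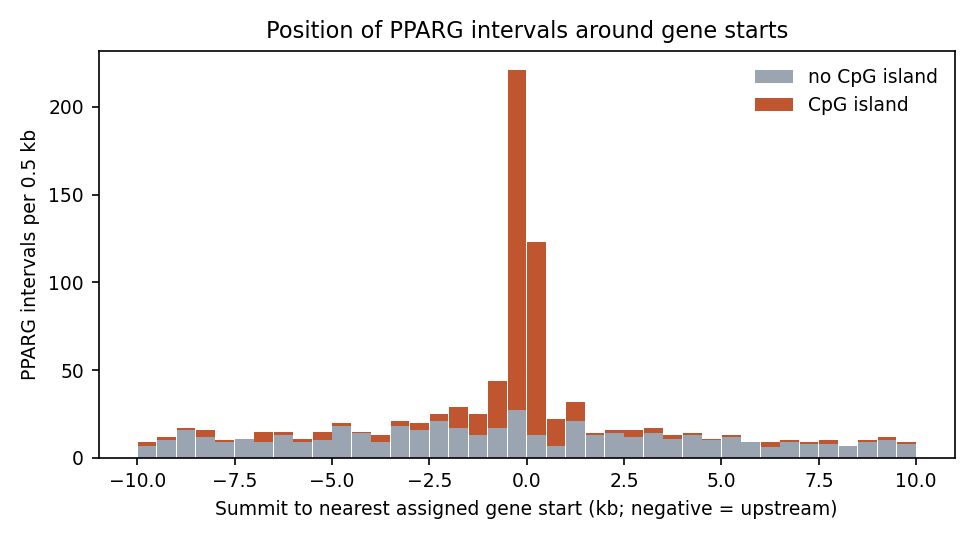
Number of PPARG intervals per 0.5 kb bin (vertical axis) against the distance in kb from the summit to the nearest assigned gene start (horizontal axis, negative values upstream), stacked by whether the authors marked a CpG island. The bin just upstream of the start held 221 intervals, of which 194 had a CpG island, and the bin just downstream held 123.

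Higher intervals more often held a CpG island and lay near a gene start. The share within 1 kb of a start was 10.7% (8.39 to 13.5) in the lowest quartile of height, 14.0% in the second, 16.3% in the third and 30.8% (27.1 to 34.7) in the highest. The share with a CpG island was 15.7% in the lowest quartile and 40.2% (36.3 to 44.3) in the highest. Of the 100 highest intervals, 46 lay within 1 kb of a start, 58 held a CpG island and 15 had no gene assigned. Intervals with both a CpG island and a promoter had a median height of 27, above the 21 to 24 spanned by the medians of 2000 random sets of as many intervals. Promoter intervals without a CpG island had a median of 21, within the 20 to 25 of random sets. The 1394 intervals with neither mark also had a median of 21, at the lower end of the 21 to 23 of random sets. All 1720 intervals without a CpG island had a median of 21, below the 22 to 23 of random sets.

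**Figure D2:**
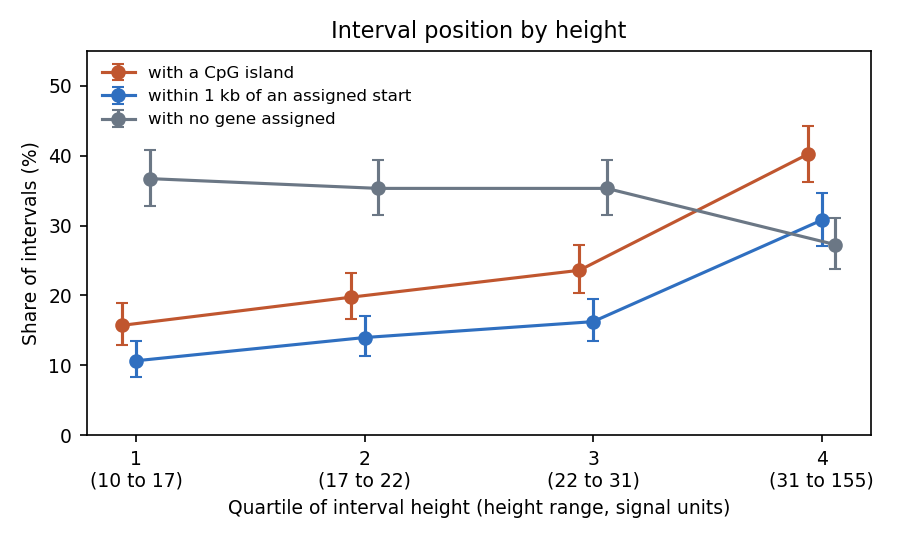
Share of PPARG intervals in percent (vertical axis) by quartile of height (horizontal axis, with the height range in signal units), for intervals with a CpG island, within 1 kb of an assigned start and with no gene assigned. Bars are Wilson 95% intervals over 572 intervals per quartile. The CpG island share was 15.7% in the lowest and 40.2% in the highest quartile.

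Of the 20 highest intervals assigned to a named gene, 14 lay within 1 kb of a gene start and 18 held a CpG island. The highest, at 155, was 177 bp upstream of IREB2, which encodes an iron-responsive RNA-binding protein (chromosome 18, 29883610 to 29885347). The others within 1 kb of a start included HNRNPH3, a splicing regulator, with 109 at 70 bp upstream, RBM39, a splicing coactivator, with 94 at 53 bp upstream, and DARS, the aspartyl-tRNA synthetase gene, with 97 at 149 bp upstream. DENR, a translation factor, had 95 at 917 bp upstream, and SUPT5H, a transcription elongation factor, had 93 at 8 bp upstream, in an interval also assigned to RPS16. QRICH1 had 93 at 46 bp upstream, in an interval also assigned to QARS. An interval of 112 was assigned to RPL13A, whose start was 8929 bp away, and lay 188 bp upstream of LOC100037666. COQ9, a coenzyme Q synthesis factor, shared an interval of 86 with CIAPIN1, and SLC25A11, the mitochondrial oxoglutarate carrier, shared 87 with RNF167, PFN1 and GP1BA. MINOS1, an organiser of the mitochondrial inner membrane, had 86 at 51 bp upstream. TMEM18 (90 at 120 bp upstream), TMCO1 (88 at 78 bp upstream) and PSMD5, a proteasome chaperone (89 at 71 bp upstream), completed the promoter sites. The remaining 6 lay farther away, at WNT10B (104, downstream), KRT80 (94, downstream), ITGAE (92, in the gene), NCOA4 with MSMB (90), CAGE1 (86, in the gene) and PPP1R14B with PLCB3 (85).

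Genes of fatty acid oxidation were the list with the highest share of members holding an interval. Of 33 named members, 14 had one (42.4%), against 1520 of 16387 named genes (9.28%), a 4.57-fold excess with an odds ratio of 7.26 (Fisher's exact test, adjusted p = 8.9e-06). SLC25A20, the carnitine-acylcarnitine carrier, had the highest interval, with a height of 63, at 56 bp upstream of its start (chromosome 19, 50991692 to 50992921). ETFDH, which passes electrons from fatty acid oxidation to the respiratory chain, had 57 at 520 bp into the gene (chromosome 17, 40101665 to 40102872). PEX11A, a peroxisome division factor, had 50 in an interval it shared with PLIN1, and CPT1A, which commits long-chain fatty acids to mitochondrial oxidation, had 46 at 32923 bp into the gene (chromosome 21, 45455128 to 45456570). The other 10 were ETFA, CPT2, ACADVL, ETFB, ECI1, HADH, HADHA, HADHB, CPT1B and ECI2, with heights from 15 to 33. HADHA and HADHB shared an interval, and 7 of the 16 intervals at the list's genes held a CpG island. The intervals of SLC25A20, ETFDH, ACADVL, ETFB, ECI1 and CPT1B were also assigned to genes outside the list. Of the 1518 intervals with a gene assigned, 442 had at least 2 genes. Counting only intervals within 1 kb of a gene's own start, 8 of the 33 members (24.2%) had one against 2.31% of all genes (odds ratio 13.8, 95% interval 5.34 to 31.8, Fisher's exact test, adjusted p = 1.1e-05). With intervals carrying a CpG island or a promoter mark left out, 3 members had one, a 2.70-fold excess that did not pass the threshold (Fisher's exact test, adjusted p = 0.222).

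Textbook PPAR target genes also held intervals more often than other genes, with 13 of 39 (33.3%), a 3.59-fold excess (Fisher's exact test, adjusted p = 0.00026). Besides SLC25A20 and CPT1A, the members with the highest intervals were HILPDA, a lipid droplet protein gene, with 59 at 2301 bp upstream (chromosome 4, 92705159 to 92706379), and PLIN1, the main lipid droplet coat protein gene of adipocytes, with 50 at 1910 bp into the gene (chromosome 18, 20201789 to 20202965). ANGPTL4, a secreted inhibitor of lipoprotein lipase named here outside the rule, had 42 at 2471 bp into the gene. The list shared 10 genes with the oxidation list, of which 6 had an interval. By Fisher's exact test adjusted over 3 sets, 7 of the 29 target genes outside that list had one (24.1%, adjusted p = 0.0147), and of the 23 oxidation genes outside the target list, 8 had one (34.8%, adjusted p = 0.0011). FABP4, LPL and PDK4, also named outside the rule, had no interval assigned. Within 1 kb of their own start 4 target genes had an interval, and 4 had one without a CpG island or promoter mark, 4.43-fold and 3.04-fold excesses that did not pass the threshold (Fisher's exact test, adjusted p = 0.110 and 0.222).

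**Figure D3:**
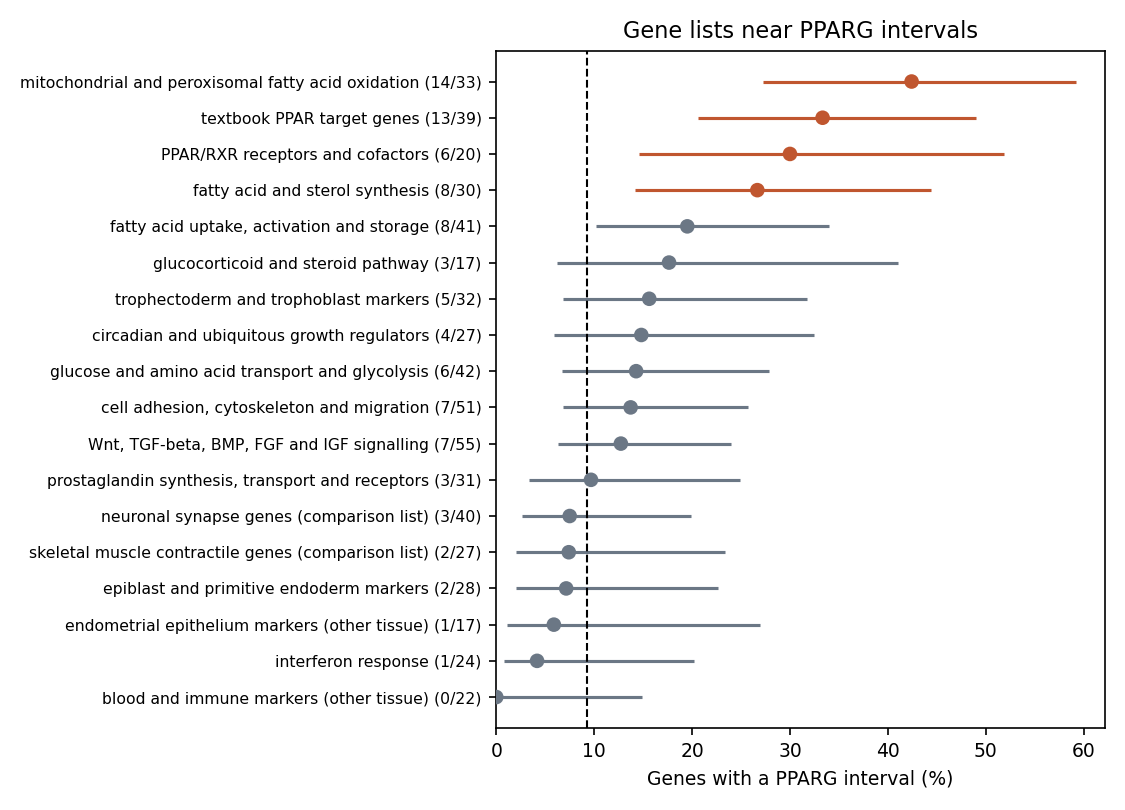
Share of named genes with an assigned PPARG interval in percent (horizontal axis) for each of the 18 gene lists (vertical axis, with counts), with Wilson 95% intervals over genes. The dashed line is the 9.28% of all named genes, and the 4 lists drawn in orange passed an adjusted p of 0.05, led by fatty acid oxidation at 42.4%.

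Fatty acid and sterol synthesis genes had intervals in 8 of 30 members (26.7%, 2.87-fold, adjusted p = 0.0295), and nuclear receptors and cofactors of the PPAR complex in 6 of 20 (30.0%, 3.23-fold, adjusted p = 0.0352), both by Fisher's exact test. In the first list, FADS2, a polyunsaturated fatty acid desaturase gene, had 5 intervals with a highest value of 28, MVK of sterol synthesis had 27, SCD, the stearoyl-CoA desaturase gene, had 21, and ELOVL6, a fatty acid elongase gene, had 19. The only interval of FADS1, named here outside the rule, was also among those of FADS2, so both members counted through 1 site. Whether the call holds with that site counted once was not tested. In the second, MED1, the Mediator subunit that contacts nuclear receptors, had 49 at 8 bp upstream of its start, PPARGC1B, a coactivator of mitochondrial genes, had 42 in the gene, and RXRG had 21. PPARG itself and RXRA had no interval assigned. By Fisher's exact test, both calls were lost at or above the median height (adjusted p = 0.834 for synthesis and 0.454 for receptors) and against genes of the other lists (1.74-fold and 1.96-fold over the genes of all lists, adjusted p = 0.399 for both). They were also lost within 1 kb of the gene's own start (1.44-fold and 4.32-fold) and without CpG islands and promoters (2.97-fold and 4.45-fold), and the synthesis call with intervals in the gene or within 2 kb upstream (2.31-fold). Fatty acid uptake, activation and storage genes, with 8 of 41 (19.5%, 2.10-fold), did not pass the threshold (Fisher's exact test, adjusted p = 0.183). PLIN1 with 50, GPAM with 40, ACSL6 with 32 and PLIN3 with 28 held the highest intervals there.

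The other 13 lists did not pass the threshold, with adjusted p of 0.525 or above. Trophectoderm and trophoblast markers had intervals in 5 of 32 members (15.6%, Fisher's exact test, adjusted p = 0.525), at GATA3, a trophoblast transcription factor gene, with 29, at the keratin genes KRT19 with 25, KRT8 with 22 and KRT18, and at HSD3B1 of steroid synthesis with 21. KRT8 had 4 intervals, and the 3 of KRT18 were all among them. Prostaglandin synthesis, transport and receptor genes had 3 of 31, at PTGR2 with 34, PLA2G15 with 27 and PTGFRN with 15. Glucose and amino acid transport and glycolysis genes had 6 of 42, led by SLC1A4 with 37, SLC43A2 with 36, SLC7A6 with 27 and SLC2A10 with 23. The signalling list had 7 of 55, led by WNT7A with 40, APC with 38, LRP5 with 31 and FGFR2 with 28. The adhesion and cytoskeleton list had 7 of 51, led by CFL1 with 53, OCLN with 36, TLN1 with 28 and EZR with 22. The growth and circadian list had 4 of 27, among them MTOR with 35, DBP with 22 and MDM2 with 20. The glucocorticoid and steroid list had 3 of 17, at HSD11B2 with 40, HSD17B1 with 25 and HSD3B1. Epiblast and primitive endoderm markers had 2 of 28, FOXA1 with 31 and LIN28A with 28, and the interferon response had 1 of 24, STAT2 with 23. Of the lists for other tissues, endometrial epithelium had 1 of 17, FXYD4 with 26, and blood and immune cells had 0 of 22. Skeletal muscle genes had 2 of 27, MYOZ1 with 34 and TNNT1 with 30, and neuronal synapse genes had 3 of 40, at DLG4 with 30, SYT1 with 23 and GABRB2 with 19. Several of these intervals were shared with other genes. PLA2G15 and SLC7A6 had the same interval, and that of DLG4 was also assigned to ACADVL. The intervals of APC and MTOR lay 106986 and 131119 bp downstream of the gene starts, were marked with a CpG island and a promoter, and were also assigned to SRP19 and EXOSC10. The highest intervals of STAT2, DBP, TNNT1, CFL1, KRT19 and PLA2G15 also lay downstream and were assigned to other genes too. Those of GATA3, SLC1A4 and MYOZ1 lay downstream as well, 27277, 21240 and 14579 bp from the gene starts. On simulated assignments the test called 20.5% of lists with a 2-fold excess, so most excesses of that size would be missed.

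Intervals were unevenly spread over chromosomes. Chromosome 11 had 148 intervals, or 2.40 per Mb up to its last interval (exact Poisson 95% interval 2.03 to 2.82), 2.67 times the 0.899 per Mb of all chromosomes. Chromosome 20 followed with 1.67 per Mb. The X chromosome had 26 intervals and the lowest density, 0.214 per Mb (0.140 to 0.314). These densities were not set against the number of genes on each chromosome. Whether the differences follow gene number was not tested. Neighbouring intervals were a median of 355 kb apart, and 124 neighbours were closer than 5 kb. The names with the most intervals were those of tRNA genes with several copies, TRNAC-GCA with 9, TRNAG-CCC with 7 and TRNAM-CAU with 6. These names lay on 5, 6 and 3 chromosomes, so each count pools copies at different places. Reads from near-identical copies cannot be assigned to one of them with certainty, but this can bear on few of the intervals. Of the 50 intervals with any tRNA name, only 8 lay within 1 kb of the tRNA gene's start.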

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

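The counts by distance to the gene's own start, within 2 kb upstream, by CpG island or promoter, against other lists and without input intervals were chosen after the data were seen. Intervals at or above the median height numbered 1200, with a median height of 30, and 35.8% lay within 5 kb of a start. A 3-fold ChIP height over a listed input height left 2285 intervals, leaving out the input intervals left 2283, and all 2288 lay on assembled chromosomes. The share near a start was 17.9% within 1 kb and 41.1% within 10 kb, and 17.3% within 5 kb for intervals without a CpG island. The excess on chromosome 11 was 3.03-fold at or above the median height. The 4 lists past the threshold became 1 within 1 kb of the gene's own start, 2 against genes of the other lists, and 0 without CpG islands and promoters, where Fisher's exact test gave 3 at an unadjusted p under 0.05. Fatty acid oxidation lost its call in that last setting alone of the 6 (2.70-fold), and PPAR targets there (3.04-fold) and within 1 kb (4.43-fold). Against the other lists these were 2.78-fold and 2.18-fold over the genes of all lists, with adjusted p by Fisher's exact test of 0.0017 and 0.0357. The receptor list lost its call at or above the median height (2.65-fold), within 1 kb (4.32-fold), without CpG islands and promoters (4.45-fold) and against the other lists (1.96-fold). Synthesis lost it in the same settings (1.18-fold, 1.44-fold, 2.97-fold and 1.74-fold) and with intervals in the gene or within 2 kb upstream (2.31-fold). Against the other lists the counts of both lists were unchanged, and only the background rose. The fold there is over the 543 genes of all lists, the tested list included. Of these genes, 83 (15.3%) had an interval, against 9.28% of all named genes. In the other settings fewer genes were counted where the fold did not fall, and elsewhere the cause was not tested. Uptake and storage passed at or above the median height (3.01-fold) and with intervals in the gene or within 2 kb upstream (2.96-fold), with adjusted p by Fisher's exact test of 0.0457 and 0.0373. No paired analysis was possible because each condition has 1 library. Motif settings, placement matched on GC content, length-matched lists and windows on both sides of genes were not run. Read depth is unknown, so no lower limit for a site can be given.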

Other observations

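The genes named in this paragraph other than FADS2, the gene families and all tests that use them, and the gene list tests within 1 kb of a start or without CpG islands were chosen only after the data were seen. ACOT11, an acyl-CoA thioesterase gene, had 5 intervals in the gene over 95.3 kb of chromosome 1, the highest 43. ABCA4, a lipid transporter gene, had 5 in the gene over 49.0 kb of the same chromosome, the highest 52. FADS2 had 5 over 124 kb of chromosome 21, of which 4 were in the gene, and the neighbouring FADS3 had 3. LPCAT3, which inserts polyunsaturated fatty acids into phospholipids, had 3 over 3.90 kb of chromosome 3, the highest 46. VMP1, an autophagy gene, had 5 over 13.6 kb of chromosome 11, 4 of them downstream of the gene. NOS2, the inducible nitric oxide synthase gene, and ERBB2, a growth factor receptor gene, had 4 each on chromosome 11, up to 37 and 44 high. The interval of 44 lay downstream of ERBB2, 30471 bp from its start, and carried 2 promoter marks. Those inside ERBB2 were at most 21 high. ARID5B, a chromatin regulator gene, had 4, up to 63. tRNA names were assigned to 50 intervals (2.19%), of which 8 lay within 1 kb of the tRNA gene's start.

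Cytosolic ribosomal protein genes had an interval in 15 of 79 cases (19.0%, 2.05-fold over all named genes), which did not pass the threshold by Fisher's exact test (adjusted p = 0.0658). Within 1 kb of the start 8 had one (10.1%, 4.38-fold, Fisher's exact test, adjusted p = 0.0026). Mitochondrial carrier genes had 9 of 45 (2.16-fold, Fisher's exact test, adjusted p = 0.182), among them SLC25A4, SLC25A11, SLC25A20 and SLC25A42. Both families passed over all intervals only in the upper count, which adds names that the gene table lacks as members with an interval. There 17 of 81 and 10 of 46 had one (Fisher's exact test, adjusted p = 0.0158 and 0.0464). Respiratory chain and ATP synthase genes had 5 of 62, mitochondrial ribosomal protein genes 10 of 75, proteasome genes 3 of 50, tRNA synthetase genes 3 of 36, peroxin genes 2 of 17 and keratin genes 5 of 38, with adjusted p by Fisher's exact test of 0.502 or above. Within 1 kb of the start, 6 mitochondrial ribosomal protein genes (3.46-fold, adjusted p = 0.0142) and 5 mitochondrial carrier genes (4.80-fold, adjusted p = 0.0101) had an interval, both past the threshold of Fisher's exact test. Respiratory chain and ATP synthase genes had 3 of 62 there (Fisher's exact test, adjusted p = 0.272), and 5 of 64 with the unmatched names counted (adjusted p = 0.0258 by Fisher's exact test).

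The excess at fatty acid oxidation genes was weighed against technical explanations. Respiratory chain, ATP synthase and mitochondrial ribosome genes had an excess near their starts too (9 of 137, 2.84-fold, Fisher's exact test, adjusted p = 0.0101). The list exceeded these genes over all intervals (42.4% against 10.9%, Fisher's exact p = 8.6e-05, or 0.0002 with the unmatched names counted). That comparison is not matched on gene length and counts intervals away from promoters. Within 1 kb the list exceeded them as well (24.2% against 6.57%, Fisher's exact test, adjusted p = 0.0087). This argues against binding at promoters of mitochondrial genes in general as the whole cause. Against mitochondrial carriers, which share SLC25A20 with the list, the difference did not pass with the unmatched names counted (Fisher's exact p = 0.0813 over all intervals, 0.134 within 1 kb and 0.0843 without CpG islands), so carriers are not covered by this. Gene length as the whole cause is argued against by the odds ratio of 13.8 (5.34 to 31.8) within 1 kb of the gene's own start. CpG islands as the whole cause are argued against by the odds ratio of 4.54 (1.66 to 10.8) without them. The counts behind these ratios rest on mostly different members, since only ECI2 had an interval within 1 kb of its start without a CpG island. Gene length and CpG islands acting together are therefore not argued against. In the count without CpG islands, HADHA and HADHB both counted through 1 interval. Whether the excess holds with that interval counted once was not tested. Crowding is not argued against by either ratio. The intervals near the starts of SLC25A20, ETFDH, ACADVL, ETFB, ECI1 and CPT1B were also assigned to other genes. With CpG islands and promoters left out, the excess did not pass the threshold (2.70-fold, Fisher's exact test, adjusted p = 0.222). By Fisher's exact test the list exceeded ribosomal protein genes over all intervals (adjusted p = 0.0189) and without CpG islands (21.2% against 3.80%, adjusted p = 0.0087). Those comparisons are not matched on gene length and count intervals away from promoters, so they do not bear on recovery of promoters. Within 1 kb the list exceeded ribosomal protein, proteasome and tRNA synthetase genes together (24.2% against 6.67%, Fisher's exact test, adjusted p = 0.0087). Nonspecific recovery of active promoters stays open for the promoter intervals, since within 1 kb the difference from ribosomal protein genes alone (10.1%) did not pass the threshold (Fisher's exact p = 0.074, or 0.156 with the unmatched names counted), and binding of PPARG was not tested by sequence.

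Higher intervals more often held a CpG island and lay near a gene start, and nonspecific recovery of active promoters is a candidate explanation for this. Ribosomal protein, proteasome and tRNA synthetase genes together had an interval within 1 kb of the start in 6.67% of cases against 2.31% of all named genes (odds ratio 3.08, 1.49 to 5.73, Fisher's exact p = 0.0016), or an odds ratio of 3.59 (1.85 to 6.40) with the unmatched names counted. Over all intervals 12.7% of these genes had one (odds ratio 1.43, 0.858 to 2.28), and without CpG islands 3.64% (odds ratio 0.631, 0.227 to 1.41). Neither of those shares differed from all named genes past the threshold. Taken alone, ribosomal protein genes passed the threshold with 8 of 79 (odds ratio 4.84, 2.00 to 10.2), and proteasome genes with 2 of 50 (odds ratio 1.76, 0.207 to 6.77) and tRNA synthetase genes with 1 of 36 (odds ratio 1.21, 0.030 to 7.22) did not, and differences between these families were not tested. Binding of the receptor at active promoters could give the same counts, and these values do not separate them.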
